A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

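The series holds 2 two-colour DNA microarrays of a Saccharomyces cerevisiae mutant named msn2/4, after the genes of the general stress transcription factors Msn2 and Msn4. Per the labels' protocols, a culture growing at 24 °C in rich medium was divided; zymolyase, an enzyme preparation that digests the glucan of the yeast cell wall, was added at 5 units per ml to one part, and the cells of both parts were collected at 3 hours. Total RNA of both parts was labelled by reverse transcription with Cy5 or Cy3. Per the labels, array 1 carried untreated RNA in Cy5 and zymolyase RNA in Cy3, and array 2 the same pair with the dyes exchanged. The series' design text gives 1 culture for this mutant, whereas the text attached to each sample speaks of several cultures per condition; the design text was followed. The 2 arrays are therefore a technical dye swap of 2 RNA extracts and count as 1 replicate. No test between the conditions was possible, and no p-value is given. Every SD below is over the 2 hybridisations and measures hybridisation and dye error only, not the spread between cultures.

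The deposited table gives 1 log2 ratio per gene and array; its scale, centring and direction are not stated in the sources used here, nor are the scanner, the background correction, the normalization or the filter that left many genes without a value. The log base was settled from the values. On array 1 all 387 values below -2 were the log2 of a ratio that is a whole multiple of 0.0001, within the rounding of the deposited log2 value to 4 decimals, where chance would give 8.95%. On array 2 this held for all 239 values below -2 after the sign was turned and for 3 of the 40 values below -2 as deposited. The array 2 column thus holds the reciprocals of the ratios first computed. The table has no spot intensities, so the signal behind a ratio is unknown and no intensity-dependent normalization could be applied.

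The sign of array 2 was turned, and the mean and SD of the 2 arrays were taken per gene; if the turn is right, a dye effect shared by both arrays cancels in that mean. The analysis design made before the data were examined foresaw a turn if the columns correlated negatively. They correlated weakly positively as deposited, and the turn was chosen after seeing the data, from genes with the largest ratios, cell wall genes foremost. Of the 37 genes beyond 4-fold on both arrays 26 had opposite deposited signs, but beyond 2-fold only 142 of 365 did (38.9%), which speaks against the turn unless a dye effect shared by the arrays outweighs the difference between the conditions in those genes. The agreement of the 2 arrays on cell wall genes is therefore not independent evidence. The rounding shows only that array 2 was inverted at some step, which a turn made before deposit would also give. The reading without the turn is an alternative added likewise. Which condition is the numerator stays unstated. Cell wall integrity transcripts are reported in published work to be raised by zymolyase, so positive ratios below are likely zymolyase over untreated, which requires the deposited values to be Cy3 over Cy5. The direction of those genes is thereby an assumption and not a finding, and with the opposite numerator every sign below is turned. The main setting used the values without recentring. The median of the mean ratios over all genes was -0.37, and positions relative to it are given where they matter.

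Of 6209 rows, 2 are control spots and 6207 carry a yeast open reading frame name, none of them repeated. Gene symbols were taken from a RefSeq gene table of assembly R64 by locus tag, which matched 5654 names; the other 553 kept the name of the file. The array probes' build is not given in the sources used here, so no coordinates are printed. A gene was counted as positive or negative when its mean ratio was at least 2-fold (1 on the log2 scale) and both arrays had the same sign. As a technical background the same rule was applied after turning array 2 back, so that the half-difference of the arrays takes the place of the mean; with the turn right it holds dye bias and hybridisation noise, including the shared dye effect that the mean cancels, so it is not the level expected in the mean. Before the data were examined, 40 gene lists were fixed. For each of the 36 with at least 3 genes valued on both arrays, the median was set against 10000 random lists of the same size from all genes with a mean. These could not be matched on signal, and a percentile describes these 2 extracts only. Random lists matched on gene length (2000 draws, 10 length bins) were added after seeing the data. The genes named are the 12 most positive and 12 most negative genes that passed the rule, up to 4 passing members of a list described (or 2 members where none passed), and MSN2, MSN4, SLT2, RLM1, HOG1, CRH1, PIR3, HSP12 and CTT1; others are named as chosen after their values were seen.

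The alternatives were centring and rescaling each array, a 1.5-fold limit, 2-fold on each array, removal of genes whose arrays differ by over 1, each array alone, the opposite sign throughout, and list means. The calling rule was tested on simulated data of this comparison over 2254 genes, with dye bias and noise drawn from the observed half-differences, scaled by assumed factors of 0.8 for the dye bias and 0.6 for the noise of each array: 83% of 100 genes changed 2.83-fold and 97% of 100 genes changed 5.66-fold were recovered, and 2.58% of the unchanged genes were counted. The simulation took the turn as right, centred unchanged genes on 0 and gave both arrays the same noise. The real arrays were used uncentred, with medians of -0.31 and -0.39, and had SDs of 1.68 and 1.20. The 2.58% is therefore not the share of unchanged genes counted in these data. Likewise, the 83% and 97% are not recovery rates in these data. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.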

Results

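The transcript response of msn2/4 mutant yeast to zymolyase was measured on 2 arrays, a dye swap of 1 treated and 1 untreated RNA extract. The question set by the series is which transcripts differ after 3 hours of cell wall digestion in cells without the general stress factors Msn2 and Msn4; a wild-type strain is not analysed here, so no value below measures what those factors contribute. Array 1 gave a ratio for 2428 genes and array 2 for 2918, and 2254 genes had a ratio on both, 36.3% of the 6207 on the array. MSN2 and MSN4 themselves had no ratio on either array. Both channels held RNA of the same mutant, so a ratio could not have checked the genotype. Ratios are log2 values, and positive ones are likely zymolyase over untreated; that reading takes the reported induction of cell wall genes by zymolyase as given, and the sign of array 2 was turned partly because those genes opposed between the deposited columns. The turn is itself an assumption that these values do not settle, and the ranks and SDs below hold only with it. Values are the mean ± SD of the 2 hybridisations of 1 culture (n = 2 arrays, technical).

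Of the 12 most positive genes 7 were on a cell wall list, and PRM10, CRG1, NFG1, GPD1 and PUN1 were on none. PRM10 had the largest mean ratio, 4.45 ± 0.51 (21.8-fold). KDX1, a pseudokinase paralog of the cell wall integrity MAP kinase, followed at 3.72 ± 0.34 (13.2-fold). YPS3, a cell-surface aspartyl protease (yapsin), stood at 3.57 ± 0.70, CRG1 at 3.41 ± 0.74 and NFG1 at 3.36 ± 2.15. PIR3, a covalently bound cell wall protein, had a mean of 3.21 ± 0.73 and SLT2, the MAP kinase of the pathway, 3.04 ± 1.47 (8.21-fold). GPD1, the glycerol-3-phosphate dehydrogenase of glycerol synthesis, had 3.00 ± 0.58, and the wall proteins SED1, NCW2 and CWP1 had 2.99 ± 0.19, 2.98 ± 1.98 and 2.89 ± 0.81. PUN1 closed the 12 most positive genes at 2.73 ± 1.61. All 12 were at least 2-fold positive on each array, and 6 of them were on the list of cell wall integrity targets. With array 2 as deposited none of the 12 could pass the rule, since their signs on the 2 arrays then differed. Their means then lay between -1.52 and 1.14 (PRM10 0.36, KDX1 0.24).

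In all, 65 genes were at least 2-fold positive and 307 at least 2-fold negative, counted here and below on the mean of the arrays and only with the same sign on both. Another 140 genes had a mean past 2-fold but opposite signs on the arrays (4 positive and 136 negative means) and were not counted. After centring each array on its median the counts were 112 and 172, so that the positive share went from 17.5% to 39.4%; all 65 positive genes and 172 of the 307 negative ones were among them. The technical background, with array 2 turned back, was 277 and 309 genes; it keeps a dye effect shared by both arrays, which the mean cancels. Among genes at least 4-fold on each array the counts were 11 positive and 15 negative, against 5 and 6 in that background. The turn was chosen partly from these genes, so this excess is no evidence for it. At 2-fold on each array the order was the other way: 38 positive and 104 negative, against 101 and 122. With the mean at least 4-fold and the same sign on both arrays, the counts were 26 and 91, against 24 and 76. After centring, the technical background was 261 and 367 genes, against the 112 and 172.

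**Figure D1:**
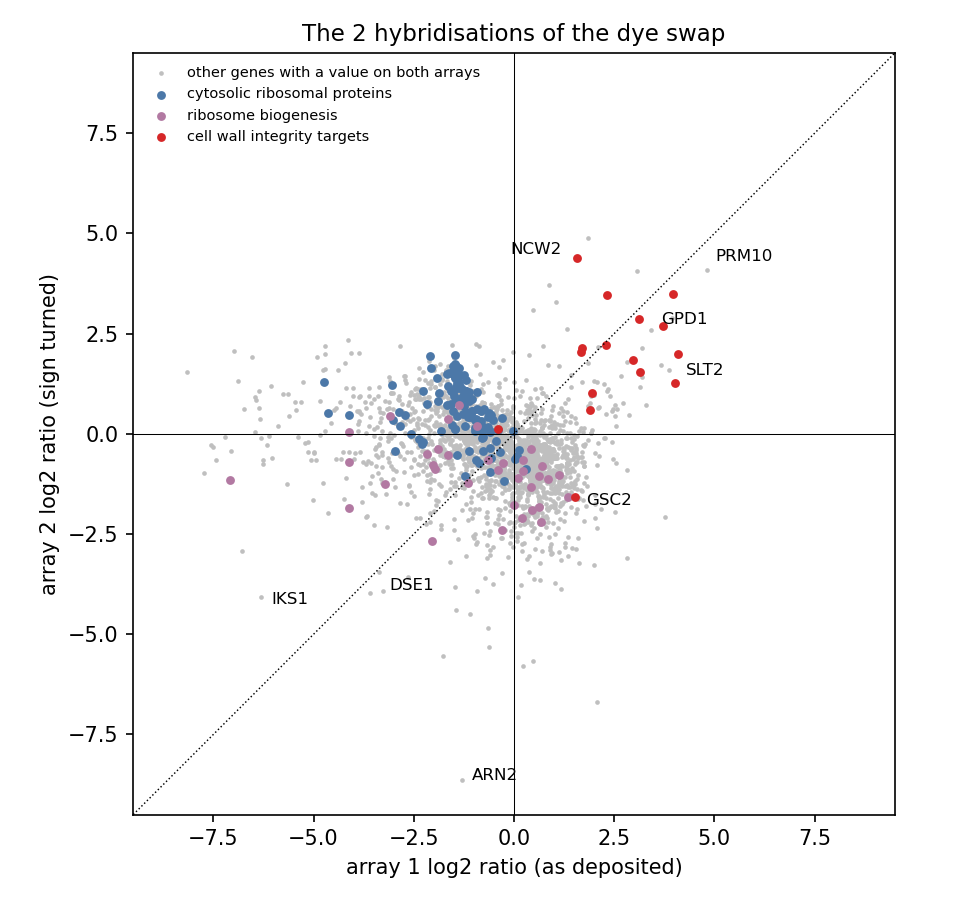
Log2 ratio of each of the 2254 genes on array 1 (x axis) and on array 2 with its sign turned (y axis); each point is 1 gene, the dotted line marks equal ratios, and 3 gene lists are coloured. The cell wall integrity targets lie toward the upper right apart from GSC2 and 1 gene near 0. Most cytosolic ribosomal protein genes lie above the dotted line, with list medians of -1.28 on array 1 and 0.56 on array 2.

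Across all genes the 2 arrays did not correlate positively. Pearson's r of the turned ratios was -0.19 and Spearman's rho -0.31 over 2254 genes, which are not independent replicates, and 39.8% of the genes had the same sign on both arrays. Among the 37 genes beyond 4-fold on both arrays, r was 0.40 and 26 genes (70.3%, exact 95% binomial interval 53.0 to 84.1%) had the same sign; without genes of the cell wall lists it was 20 of 31 (64.5%, 45.4 to 80.8%), an interval that includes 50%. Beyond 2-fold on both arrays most genes had opposite signs: 142 of 365 (38.9%, 33.9 to 44.1%) had the same sign, and 128 of 350 (36.6%, 31.5 to 41.9%) outside the cell wall lists. These intervals take the genes as independent, which they are not, so they are too narrow. The SD across genes was 1.07 for the half-difference of the arrays and 0.893 for their mean. The half-difference followed gene length (rho = 0.46 across 2174 genes), and the mean did not (rho = 0.03).

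Of 16 measured cell wall integrity targets, a list of genes under the Slt2 kinase and the Rlm1 transcription factor, 14 were at least 2-fold positive and none was negative. Only 1 of the 16 passed with array 2 turned back, but the 14 could not, since the rule needs the same sign on both arrays. The list median was 2.38 (quartiles 1.76 and 2.98), against an all-gene median of -0.37, and lay above all 10000 random lists. Both arrays carried it, with medians of 2.31 and 2.01. It was 0.35, at percentile 81.8, with array 2 as deposited. Besides the members named above, CRH1, a chitin-glucan transglycosylase, had 2.35 ± 1.14 and GFA1, the first enzyme of chitin precursor synthesis, 2.64 ± 1.93. The 2 members that did not pass were GSC2, a glucan synthase subunit at -0.02 ± 2.19, with ratios of 1.53 and -1.56 on the 2 arrays, and CHS3, a chitin synthase at -0.14 ± 0.36; both were named after their values were seen. PIR1, PIR3, HSP150 and CIS3 are members of 1 repeat-containing family, and cross-hybridisation among them cannot be separated on such an array. RLM1 had no ratio on either array.

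Other cell wall lists were positive in part. Of 12 measured cell wall mannoproteins 7 were at least 2-fold positive, led by YPS3, PIR3, SED1 and CWP1, and the median was 1.67, above all random lists; 6 of the 7 are also cell wall integrity targets. In glucan remodelling 3 of 10 were positive, namely CRH1, EXG1, an exoglucanase at 1.51 ± 1.32, and BGL2, a glucan transferase at 1.25 ± 0.92, and SCW11 was negative at -1.94 ± 1.42. The median of that list was 0.52, with 1.46 on array 1 and -0.22 on array 2, and 2 members passed as positive with array 2 turned back. In chitin metabolism 3 of 8 were positive: GFA1, PCM1, the phosphoacetylglucosamine mutase, at 1.67 ± 1.02, and CHS7, a chaperone of chitin synthase export, at 1.40 ± 1.03. Of 6 measured components of the cell wall integrity pathway, SLT2 and the surface sensor MID2 (1.10 ± 0.34) were positive, and the median was 0.37, with 0.63 on array 1 and 0.15 on array 2. Together 19 of the 65 positive genes and 1 of the 307 negative genes stood on 1 or more of these 5 cell wall lists, out of 40 such genes measured. With the turn, the list medians lay at percentile 99.99 for glucan remodelling, 97.54 for chitin metabolism and 99.68 for the pathway. The list medians with array 2 as deposited were -0.20 for mannoproteins (percentile 25.6), 0.84 for glucan remodelling (98.98), 0.61 for chitin metabolism (92.5) and 0.16 for the pathway (59.0).

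**Figure D2:**
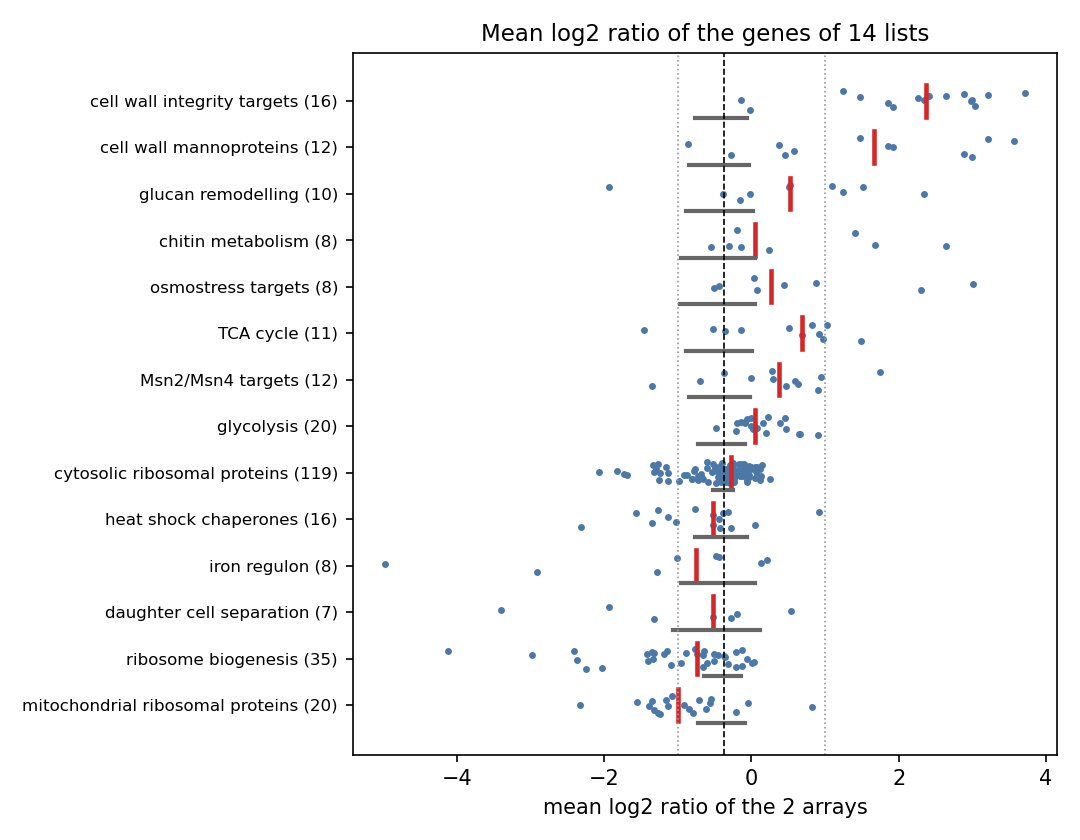
Mean log2 ratio of the 2 arrays (x axis) for the genes of 14 lists (y axis, with the number of genes valued on both arrays); points are genes, red bars list medians, grey bars the central 95% of random lists of the same size, the dashed line the all-gene median of -0.37 and dotted lines 2-fold. The cell wall integrity targets and mannoproteins have medians of 2.38 and 1.67, and mitochondrial ribosomal proteins have the lowest at -0.995.

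Osmotic stress genes are targets of the Hog1 kinase, the MAP kinase of the osmotic stress pathway. Of 8 measured, 2 were at least 2-fold positive: GPD1, above, and HXT1, a low-affinity glucose transporter, at 2.30 ± 1.26. The list median was 0.26, the 99.8th percentile of random lists, with 0.74 on array 1 and 0.46 on array 2; with array 2 as deposited it was 0.21, at percentile 63.0. HOG1 itself had 0.43 ± 1.12, with opposite signs on the 2 arrays. None of 11 measured HOG pathway components passed the rule. STE50 had a mean past 2-fold, -1.36 ± 2.83, but opposite signs on the arrays (-3.36 and 0.65), and SLN1 had -0.80 ± 0.59. The list median was 0.02, at percentile 98.0, with 0.19 on array 1 and 0.02 on array 2. With array 2 as deposited that median was -0.06, at percentile 40.1.

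Targets of Msn2 and Msn4 were mostly without a value: 22 of the 39 on the array, HSP12 and CTT1 among them, had no ratio on either array, and 12 had one on both. Of these 12, PRB1, the vacuolar protease B, was at least 2-fold positive at 1.74 ± 0.71 and none was negative; SSA4, named after its values were seen, had a mean of -1.35 with opposite signs on the arrays. The list median was 0.38, above all random lists, but it was 1.17 on array 1 and -0.05 on array 2. In the technical background 3 members passed as positive and 1 as negative, and the list median was 0.73, at percentile 98.5. When genes whose arrays differed by over 1 were left out, 2 genes remained with a median of -0.06. In trehalose and glycogen metabolism, 1 of 9 measured genes was positive, the trehalase NTH1 at 1.43 ± 0.69, and 2 were negative, NTH2 at -1.34 ± 0.93 and TPS3, a trehalose synthase subunit, at -1.02 ± 0.82. The list median was 0.47, at percentile 99.97, with 1.18 on array 1 and -0.12 on array 2; with array 2 as deposited it was 0.58, at percentile 91.0.

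In central metabolism the tricarboxylic acid cycle list had a median of 0.69, the 99.99th percentile of random lists, with 1.12 on array 1 and 0.21 on array 2; with array 2 as deposited it was 0.64, at percentile 95.6. Citrate synthase CIT1 (1.49 ± 1.47) and aconitase ACO1 (1.02 ± 1.30) were the 2 of 11 genes that passed the rule, and neither was 2-fold on array 2; SDH3, a succinate dehydrogenase subunit named after its values were seen, had a mean of -1.46 ± 2.63 with opposite signs on the arrays (-3.32 and 0.40). None of 20 glycolytic genes passed 2-fold, and 6 passed as positive with array 2 turned back. Their median was 0.05, at percentile 99.92, with 0.56 on array 1 and -0.43 on array 2. With array 2 as deposited that median was 0.58, at percentile 98.1. The members with the largest means were GLK1 at 0.90 ± 1.08 and PDC1 at 0.65 ± 0.81.

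With array 2 turned, the most negative ratios had larger SDs than the most positive ones. Of the 12 most negative genes, 6 were at least 2-fold negative on each array, and the median SD of the 12 was 4.73, against 0.734 for the 12 most positive. With array 2 as deposited the 12 most negative and 12 most positive genes had to be other genes, because the rule needs the same sign on both arrays. Their median SDs were 3.83 and 1.17. IKS1, a putative protein kinase, had the lowest mean at -5.20 ± 1.59. ARN2, a siderophore-iron transporter, had -4.98 ± 5.19, GNT1, a glycosyltransferase, -4.85 ± 2.73, UTP9, of ribosomal RNA processing, -4.12 ± 4.18, and PEX8, of peroxisome biogenesis, -3.66 ± 2.67. YIL177C, a subtelomeric helicase-like gene with near-identical copies, had -3.78 ± 0.28. The other 6, CTS2, GRX4, AIM36, YLR062C, FYV10 and BNR1, had ratios between -7.73 and -7.06 on array 1 and between -0.97 and -0.09 on array 2.

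Ribosome-related lists differed in how the arrays bore on them. In ribosome biogenesis 12 of 35 measured genes were at least 2-fold negative and none was positive. UTP9, NOP9 (-2.98 ± 1.61), RRP42 (-2.41 ± 2.42) and PWP2 (-2.37 ± 0.44) led them, and the list median of -0.74 lay at percentile 0.46. Its medians were -0.39 and -0.94 on arrays whose own medians were -0.31 and -0.39. In the technical background 6 genes of this list passed as positive and 4 as negative, and the list median was 0.26, at percentile 78.5. Of 119 cytosolic ribosomal protein genes 6 were negative, led by RPL23B at -1.69 ± 1.80, and the median was -0.27 (percentile 93.6); the arrays' medians were -1.28 and 0.56, and 57 of the genes passed in the technical background, where the list median was -1.03, below all random lists. Many of these genes have near-identical paralogs, which such an array may not separate. Mitochondrial ribosomal proteins had the lowest median shown, -0.995 (percentile 0.10), with 5 of 20 genes negative, among them MRPL7 at -1.39 ± 0.68 and RSM23 at -1.34 ± 1.28. That median was -2.16 on array 1 and 0.40 on array 2, so its sign rested on array 1, and with array 2 turned back 9 of the 20 passed as negative and the median was -1.01, at percentile 0.05.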

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

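The counts, medians and named genes with array 2 as deposited were added after seeing the data. The other settings were planned, but those that use array 2 carry its turn, which was chosen after seeing the data. For positive and negative genes (65 and 307), the counts were 109 and 515 at 1.5-fold, 38 and 104 with 2-fold required on each array, 112 and 172 after centring, 109 and 168 after centring and rescaling, 21 and 90 among the 806 genes whose arrays differed by at most 1, and 307 and 65 with every sign turned. With array 2 as deposited they were 277 and 309. From 1 array alone, over all genes valued there, positive counts ranged from 271 to 297 and negative counts from 757 to 859. The correlation of the arrays was -0.10 in place of -0.19 without genes under 0.5. The cell wall integrity median (2.38) was 2.72 after centring, 2.74 after rescaling, 1.92 over the 7 genes whose arrays agreed within 1 and 0.35 with array 2 as deposited, and 2.01 to 2.25 from 1 array alone.

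Turning every sign reverses by construction: the medians become -2.38 for cell wall integrity targets, -1.67 for mannoproteins, -0.52 for glucan remodelling, -0.048 for chitin metabolism, -0.26 for osmotic stress, -0.38 for Msn2/Msn4 targets, -0.37 for the cell wall integrity pathway, -0.021 for the HOG pathway, -0.47 for trehalose and glycogen, -0.69 for the tricarboxylic acid cycle, -0.049 for glycolysis, 0.74 for ribosome biogenesis and 0.995 for mitochondrial ribosomal proteins. Without the genes whose arrays differ, chitin metabolism (-0.23), Msn2/Msn4 targets (-0.056) and glycolysis (-0.031) changed sign over 4, 2 and 8 genes, and mating response (-0.069) became 2.16 over 2. With array 2 as deposited, mannoproteins (-0.20), the HOG pathway (-0.060) and ribosome biogenesis (0.26) did, as did iron (0.86), heat shock (1.06), daughter-cell separation (0.22), mating response (0.74), phosphate (1.04) and amino acid genes (0.53), all negative with the turn, and the HOG pathway did by its list mean (-0.071) and mating response by its (0.63). Centring, without and with rescaling, made cytosolic ribosomal proteins 0.073 and 0.22 and mating response 0.28 and 0.32. Each array alone gave glucan remodelling -0.18 and 1.11, trehalose and glycogen -0.18 and 1.18, the tricarboxylic acid cycle 0.10 and 1.12, glycolysis -0.43 and 0.56 and mitochondrial ribosomal proteins 0.46 and -2.08 (array 2 first), cytosolic ribosomal proteins 0.57 and -1.28, autophagy 0.10 on array 2, and on array 1 heat shock 0.63, amino acid genes 0.18, phosphate 0.14 and mating response 0.63; the cause was not tested. The 12 most positive and 12 most negative genes were chosen with the same sign on both arrays, so 1 array alone could not change their sign. With array 2 as deposited, ARN2 (3.67), PEX8 (1.89), YIL177C (0.20), CWP1 (-0.57), NCW2 (-1.40), NFG1 (-1.52) and YPS3 (-0.50) changed sign. The alternative that treats each spot on its own was not run, since no gene had more than 1 row. Spot signal over background, which would show the limit of each ratio, is not used here; with 1 culture no statement on repeatability between cultures is possible, and no paired analysis was possible because both arrays hold the same 2 extracts.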

Other observations

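The tests of array direction, of dye bias, of a lower RNA level in the tail of array 1 and of shared osmotic stress members were chosen after their results were seen, the length-matched lists were added after the list medians were seen, and YJL107C, CHA1, PRY2, SSA3, SSA4, the genes valued on 1 array and the control spots were chosen after their values were seen.

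Daughter-cell separation genes, which act at the septum after division, held 3 negative members of 7: DSE1 at -3.40 ± 0.05, nearly equal on both arrays, SCW11 at -1.94 ± 1.42 and DSE4 at -1.33 ± 0.99, while the list median of -0.53 was at percentile 29.9 and was 0.22, at percentile 60.2, with array 2 as deposited. Iron uptake genes held 3 negative members of 8, ARN2, ENB1 (-2.92 ± 2.09) and the ferroxidase FET3 (-1.01 ± 1.29), with a list median of -0.75 at percentile 8.91; that median was -0.05 on array 1 and -1.45 on array 2, so it rested on array 2, and with array 2 as deposited the list median was 0.86, at percentile 98.6. Of 16 heat shock chaperones, FES1 (-1.57 ± 0.17), AHA1 (-1.13 ± 0.07) and STI1 (-1.26 ± 1.21) were negative, and 8 other members passed, as positive, with array 2 turned back, where the list median was 1.06 in place of -0.52; SSA3 had 2.06 on array 1 and -6.69 on array 2, and SSA4 had 1.17 and -3.87. PRM10 was the single passing member of 7 measured mating-response genes, whose median was -0.07, and 0.74 with array 2 as deposited. YJL107C, which neighbours PRM10, had 3.77 on array 1 and -2.06 on array 2. CHA1, the serine and threonine deaminase, had 2.14 ± 0.05, and the secreted sterol-binding protein gene PRY2 had 2.66 ± 0.74.

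Genes valued on 1 array only are open to dye bias. CHS1, a chitin synthase (2.38), and PTP2, a phosphatase of the Slt2 and Hog1 kinases (2.19), had the highest ratios of the 174 genes seen on array 1 alone, and YHR033W (3.51) and YHR138C (3.23) those of the 664 seen on array 2 alone, where HOR7 had 2.54. A control spot named for a salt buffer carried ratios of 0.12 and -0.53, and a spot named for Arabidopsis -1.15 and -3.27. None of 16 sporulation genes and none of 4 alpha-specific genes had a value on both arrays, which says nothing of their level. The 16 chromosome medians lay between -0.54 on chromosome 7 and -0.17 on chromosome 3. Of the 36 lists, 13 had a median above the central 95% of random lists and 2 below it; for the half-difference, which holds dye effects, 9 and 3 did.

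As deposited, 14 of the 16 measured cell wall integrity targets were positive on array 1 and negative on array 2; GSC2 was positive and CHS3 negative on both. Dye bias and columns that run in opposite directions cannot be told apart as the source of this. With array 2 turned, the list median was 2.38, above all random lists, but the turn was chosen partly from these genes; with array 2 as deposited it was 0.35, at percentile 81.8. Outside the cell wall lists, 20 of the 31 genes beyond 4-fold on both arrays had opposite deposited signs (64.5%, interval 45.4 to 80.8%), whereas beyond 2-fold 128 of 350 did (36.6%, 31.5 to 41.9%), which goes against the turn unless a shared dye effect dominates there. Both intervals take the genes as independent, which they are not, so they are too narrow. The direction stays open. The length trend lay in the half-difference (rho = 0.46) and not in the mean (rho = 0.03); as deposited, the place of the half-difference and the mean is exchanged, so the trend does not settle the direction either. Which condition is the numerator stays open. Array 2 was inverted before deposit, and whether that inversion brought the 2 columns into 1 direction stays open too.

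Array 1 had 206 genes at or below -3 and 17 at or above 3. A lower RNA level after zymolyase, as the whole cause, predicts low ratios for the same genes on array 2, but the 168 of them valued there had a median of 0.42 relative to that array's median (bootstrap interval 0.17 to 0.70), which is far from their ratios on array 1 whichever way array 2 is read. The genes at or above 3 on array 1 had 2.38 there. Spots with a weak channel on array 1 are a candidate explanation: 81.6% of the genes of the negative tail had a value on array 2 (exact 95% interval 75.6 to 86.6%), against 95.4% of the genes between -1 and 1 on array 1. A longer negative tail was not particular to array 1. Array 2 with its sign turned had 72 genes at or below -3 and 11 at or above 3. Of those 72, 54.2% had a value on array 1 (exact 95% interval 42.0 to 66.0%). The median of the valued ones there was 0.01 relative to that array's median. The spot intensities that would decide on weak spots were not used here, and a change of RNA level in single genes of the tail stays possible.

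With array 2 turned, the medians of ribosome biogenesis and mitochondrial ribosomal protein genes were low; with array 2 as deposited, the biogenesis median was 0.26, at percentile 78.5, so that low median holds only with the turn, while the mitochondrial one was -1.01, at percentile 0.05. The mean had no length trend, so matching on length could hardly move them there, and the lists were set against length-matched lists on the array where each was lower, since each array did follow length (rho = 0.34 on array 1 and -0.46 on array 2). Ribosome biogenesis lay at percentile 0.25 of those lists on array 2 and mitochondrial ribosomal proteins at 0.00 on array 1 (below all 2000 draws), which argues against length as the whole cause on those arrays; on the other arrays they lay at 29.1 and 91.7. Weak spots on array 1 and a dye effect shared by both arrays stay open for the mitochondrial list, whose array 2 median was above 0. Among random lists not matched on length, that list lay at percentile 0.01 on array 1 and 99.8 on array 2. The cytosolic ribosomal protein list had arrays of opposite sign (-1.28 and 0.56), so its mean decides nothing on a lower demand for ribosomes. A biological source of the low biogenesis median stays open and untested in 1 culture. With the turn, no gene of that list lay above both arrays' medians and 13 of 35 lay below both. The share over all genes is not given here, and heat shock chaperones also had 0 above both and 4 of 16 below both. These counts therefore do not bear on that source.

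With array 2 turned, the median of the osmotic stress list (0.26, with 2 of 8 genes past the rule) was not carried by members shared with the cell wall or Msn2/Msn4 lists. PTP3 was the single measured member also on 1 of the 5 cell wall lists or the Msn2/Msn4 list; at 0.03 it lay below the list median, so leaving it out could only raise that. Without it the median of the other 7 was 0.45, at percentile 99.8; with any 1 more gene left out the percentile stayed between 99.2 and 99.98. As deposited, the full list lay at percentile 63.0, so there was no high median to explain.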
